A study of Homo sapiens with 35 samples.

How the data were processed

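ATAC-seq libraries were made from 50000 nuclei of H1-derived blood progenitors each, with 45 minutes of transposition and paired-end reads of 75 nucleotides, per the labels' protocols. Trim Galore 0.6.5, Bowtie2 2.2.8 and Picard 2.2.4 and the builds GRCh38.p13 and hg38 are named per the submitters' processing notes. The peak names in the deposited list carry MACS 2.1.0 and GENCODE 36. No source used here states the order of these steps, the duplicate and mitochondrial filters, any shift of reads for the transposase or the libraries that entered the pool.

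The deposited peak list gives each peak's position and summit, a score, a fold enrichment at the summit (a linear ratio to background) and a −log10 p-value and −log10 q-value. The authors' score, the deposited fold and the deposited −log10 p rank the peaks identically (Spearman correlation 1 across peaks), so any of them sets the same order. The q-values were not used here. Per the values in the list, fold and p are matched by a single background of 93.5 for the whole genome, with fold equal to (pileup + 1) / (background + 1) and p from a Poisson distribution. Under that background, 100% of 243585 pileups under 1000 came out whole to within 0.1. A constant background does not correct for regional differences in accessibility, copy number or mappability, so regions with many copies in the genome can look enriched. Peaks neither overlapped nor repeated (0 cases each). Pooling libraries means that a peak can come from a part of them, and the number of weak peaks depends on the summed depth. Depth per library is not known from this list.

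Samples were grouped by line, doxycycline treatment and day as the labels give them, but the list names no library, so the comparison of doxycycline-treated with untreated libraries could not be run and nothing printed is a difference between groups. Genes came from a RefSeq table of GRCh38.p14 with 59098 genes on chromosomes 1 to 22 and X, of which 19974 are protein-coding; the chromosome coordinates do not differ between these patch releases. This table holds gene starts and ends but no strand, transcripts or exons, and no genome sequence was used here. Promoters were therefore taken as 1 kb on each side of both ends of each protein-coding gene, in place of transcript starts. Exons and introns were pooled as gene bodies. Distal peaks were counted per 100 kb within 50 kb of both ends, in place of a count around the start. Both definitions were changed from the plan after the files were seen and before their results were. The motif comparisons and the random lists matched on CpG content that had been set out were not run. Directions at named loci use the strands of 14 genes from general knowledge.

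Numbers were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. Random placement used 100 circular shifts of all summits within each chromosome, with an exact two-sided sign test over 23 chromosomes. The 24 gene lists held 398 entries (383 distinct genes, 9 to 25 per list after matching), and 1 entry matched no single gene. Each list's median was set against 10000 random lists of its size from all protein-coding genes, two-sided, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. Genes are not independent replicates: neighbours share peaks, and p-values describe this peak set, not a population of cultures. Named genes are the 3 with the highest fold and up to 2 without a summit in each list, MYC and MAX, the 10 genes with the most distal peaks, the genes nearest to the 5 highest peaks and the anchors of the 15 windows; not every gene that meets these rules is named, and some were not used here. Other list members named beside distal densities, and SOX2, NANOG, POU5F1 and the beta-globin genes, were chosen after their values were seen.

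The list test was tested on simulated data for lists of 20 genes with fold values drawn from the 19974 genes: of 100 lists each, 7% were called with no change, 46% with a doubling (2-fold) and 80% with a 4-fold rise. These simulated calls used the p-value of each list before adjustment, whereas the gene lists of the data were called on adjusted p-values. Adjustment can only lower these shares, so they are not the power or the false-call rate of the adjusted test. Small lists therefore miss moderate differences. A simulated background of 50 was recovered as 50.0, and uniformly placed peaks lay at gene ends in 2.56%. Alternatives were the more significant 50% of the peaks, windows of 0.5 and 2.5 kb, any overlap of at least 1 bp in place of the summit, distances of 20 and 100 kb and matching on neighbouring genes within 500 kb. Summits nearest to the gene itself, matching on gene length and leaving out the X chromosome were added after the data were seen.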

Results

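Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in blood progenitors differentiated from H1, an established human embryonic stem cell line. The series addresses what ectopic MYC, a transcription factor that drives growth and is often deregulated in leukaemia, does to these progenitors when doxycycline is added. The labels describe 35 libraries, while the design text counts 44. Of the 35, 12 came from doxycycline-treated and 11 from untreated cultures of a line called doxee17 (batch 1), and 12 from untreated cultures of H1 (batch 2), over 6 days from day 10 to day 20. These form 18 groups of 1 to 3 libraries. The values analysed here are a single list of peaks with no value for any library, so treated and untreated cells, days and lines could not be compared and no replicate error can be given. The comparisons below set the genes and regions of this one peak set against one another and against random genes and positions. Every fold enrichment is the authors' value for a peak, and coordinates are on GRCh38.

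The list held 308732 peaks covering 229 Mb, of which 308145 lay on chromosomes 1 to 22 and X. Peaks had a median width of 482 bp (interquartile range 341 to 807) and a median fold enrichment over background of 3.46 (interquartile range 2.12 to 8.59; range 1.32 to 4635). Weak peaks made up most of the list: 62.2% lay under 5-fold and 21.1% under 2-fold, while 6529 peaks (2.11%) exceeded 100-fold. Among autosomes, peak density was lowest on chromosome 13 (70.9 per Mb) and highest on chromosome 19 (154 per Mb). Length was counted from the chromosome start to its last peak, without leaving out unassembled sequence. Chromosomes 21 (75.2) and 18 (77.3) came close to chromosome 13, so which was lowest rests on that count of length. The depth of single libraries is unknown. The caller's values imply a pooled background of 93.5 overlapping reads or fragments, against 124 at the weakest peak and 326 at the median peak. Exact Poisson 95% intervals, which cover counting error only, ran from 1.10 to 1.57-fold for the weakest and from 3.10 to 3.86-fold for the median peak.

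Peak summits, the positions of highest signal, gathered at the ends of protein-coding genes. Within 1 kb of an annotated gene end lay 6.98% of summits, against 2.60% ± 0.075 (SD, 100 circular shifts of the summits), a 2.68-fold excess. Summits elsewhere inside coding genes made up 50.4% (42.0% ± 0.574 after shifting). Those in other genes made up 12.01% (13.6% ± 0.218), and intergenic summits 30.6% (41.8% ± 0.569). The excess at gene ends and in coding gene bodies, and the deficit in the other 2 classes, had the same direction on 23 of 23 chromosomes (exact two-sided sign test over chromosomes, p = 2.38e-07 for each class). The shifts did not leave out sequence in which no peak can be called. Where such sequence lies outside genes, it adds to the intergenic deficit and to the excess in genes on each chromosome. Peaks at gene ends were the strongest and widest class, with a median of 20.5-fold and 1460 bp, against 3.20-fold and 473 bp in coding gene bodies. Of the peaks above 100-fold, 74.0% lay at gene ends, and of those under 2-fold, 4.21%. Starts and ends of genes were not told apart, since the annotation used gives no strand.

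**Figure D1:**
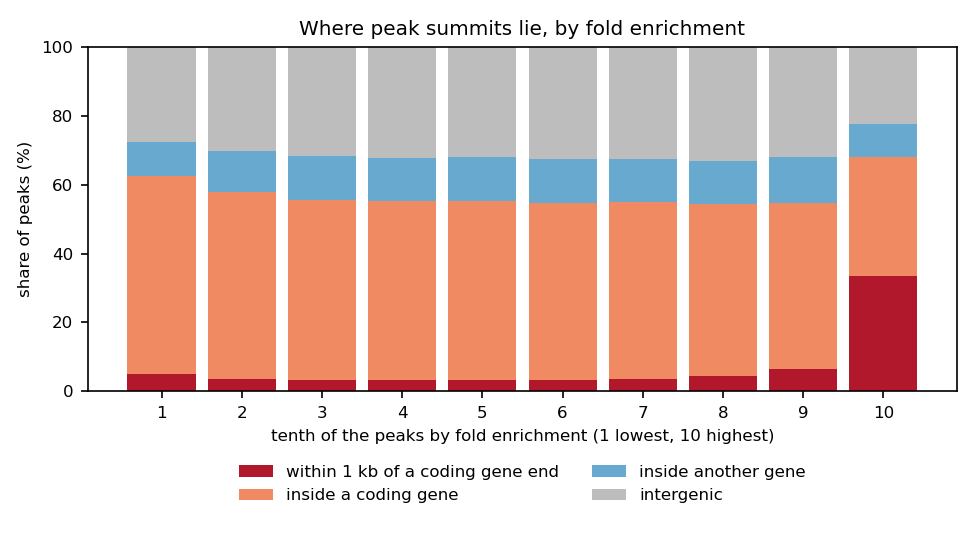
Share of peak summits (%, vertical axis) in 4 classes of sequence for 10 equal groups of peaks ranked by fold enrichment (horizontal axis, 1 lowest to 10 highest). Summits within 1 kb of a coding gene end make up 33.5% of the highest group and between 3.26% and 6.604% of the others.

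Which genes are open was asked with 24 gene lists fixed before the data were examined. Of 19974 protein-coding genes, 16586 (83.0%) had a summit within 1 kb of an end, and the median over all genes of the highest fold there, taking 0 for a gene without one, was 43.5. Growth genes stood highest. The 18 housekeeping genes had a median of 140-fold (EEF1A1, a translation elongation factor, 215; RPLP0, a ribosomal protein, 190; TUBB, a tubulin, 183), and 15 of them exceeded the median of all genes. The 25 cell cycle genes had a median of 128-fold, with the replication proteins MCM3 at 274 and PCNA at 258 and the phosphatase CDC25A at 234. The 25 ribosome biogenesis genes and other common MYC targets had a median of 118-fold, with 23 above the median of all genes (RRP9 335, CDK4 247, and NCL, which encodes nucleolin, 232). Each of these 3 lists was higher than expected from 10000 random lists of its size, at percentiles 99.96, 99.99 and 99.91 (two-sided permutation test, Benjamini-Hochberg adjusted over 24 lists, p = 0.008, 0.008 and 0.0106).

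The 5 lists that stood lowest were hepatocyte, mesenchymal, keratinocyte and pluripotency genes and, of the blood lists, mast cell and eosinophil genes. Only 7 of 16 hepatocyte genes had a summit at an end, and the median of the list was 0; ALB, which encodes serum albumin, and AHSG had none, while APOA1 reached 57.6-fold. Mesenchymal genes had a median of 0.889-fold, with 7 of 14 showing a summit (COL1A1 60.6; COL3A1 and DCN none). Keratinocyte genes had a median of 0 (5 of 11; SFN 179; FLG and DSG3 none). Mast cell and eosinophil genes had a median of 1.64 (6 of 11 with a summit, SIGLEC6 83.6, CLC 42.1, FCER1A none). Of those without a summit, GATA2 (54.9-fold), PRG2 (31.9) and EPX (19.0) had an end under a peak with its summit farther away. With any overlap counted, 9 of the 11 had a covered end. Pluripotency genes had a median of 2.99 (12 of 17). Among these pluripotency genes, DNMT3B reached 74.8-fold, SOX2 17.6, NANOG 2.42 and POU5F1 1.93, and DPPA2 had no peak at its ends. These 5 lists were lower than random lists (permutation test, adjusted p = 0.008 for hepatocyte, 0.0106 for mesenchymal and 0.0462 for each of the other 3). None of the 5 lower calls survived when only the more significant 50% of the peaks were used (permutation test, adjusted p from 0.0728 to 0.164), although all 5 medians were then 0, against 42.7 to 44.2 for random lists. With 0.5 kb windows none survived either, and pluripotency and mast cell genes kept their calls in only 1 of 7 alternatives each. By the share of genes with a summit, hepatocyte genes alone passed (43.8% against 81.2% in random lists; permutation test, adjusted p = 0.024).

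Progenitor, megakaryocyte, neutrophil and monocyte, and erythroid genes did not differ detectably from random genes by this measure. Medians were 29.5-fold for 22 progenitor transcription factors, 30.2 for 14 progenitor surface proteins, 30.6 for 14 megakaryocyte, 23.6 for 22 neutrophil and monocyte and 14.5 for 20 erythroid genes (permutation test, adjusted p from 0.273 to 0.716). All 14 megakaryocyte genes had a summit at an end, among them ITGA2B, the platelet integrin alpha chain (113-fold), THBS1 (104) and GP6 (73.3). High values among the rest included LYL1 (191) and KMT2A (190), the myeloid factors SPI1 (109), CEBPB (91.1) and CEBPA (83.7), the transferrin receptor TFRC (115), and the adhesion proteins CD47 (96.8) and ITGA4 (95.2). Several master regulators had no summit at an end because a wide peak with its summit farther away covered it. GATA2 lay under a 54.9-fold peak, MECOM under a 76.7-fold peak, CEBPE under a 74.2-fold peak, and TAL1 under a 105-fold peak. HBA1 and HBA2, the alpha-globin genes, lay under a single 51.4-fold peak whose summit lies at an end of the neighbouring gene HBQ1. With any overlap counted, all 92 entries of these 5 lists had a covered end, but no call changed.

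Other lists fixed in advance did not pass either (permutation test, adjusted p from 0.0944 to 0.864). The MYC network had a median of 98.6-fold over 12 genes, with the MYC antagonists MXD1 at 351, MXD4 at 315 and MNT at 197 and the MYC partner MAX at 166. Genes recurrently altered in acute myeloid leukaemia had a median of 97.1-fold (25 of 25 with a summit; ASXL1 241, SRSF2 200); this list passed as higher in 2 of 7 alternatives, with only summits nearest to the gene itself and without the X chromosome (permutation test, adjusted p = 0.0472 and 0.0272). AP-1 factors had 49.6-fold (JUND 215, JUN 196, and JUNB under a 237-fold wide peak). The remaining medians were those of T and NK lymphocyte (11.4-fold; CD3E 75.0, CD3G none), HOXA (8.44; HOXA4 39.5), neuronal (8.32; SYP 67.1, DCX none), endothelial (8.004; PECAM1 82.9, KDR 28.4), B lymphocyte (7.49; EBF1 60.6, MS4A1 none), macrophage (6.91; CD5L none), skeletal muscle (5.77; RYR1 38.4, MYF5 none) and HOXD genes (5.23; HOXD13 15.5). A summit at the end of a gene can also lie at a neighbour's end: this held for 11 of the 70 genes that led a list, including RRP9 (PARP3), PCNA (CDS2), GP6 (RDH13), SRSF2 (MFSD11), VRTN (ABCD4) and RAG1 (TRAF6).

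**Figure D2:**
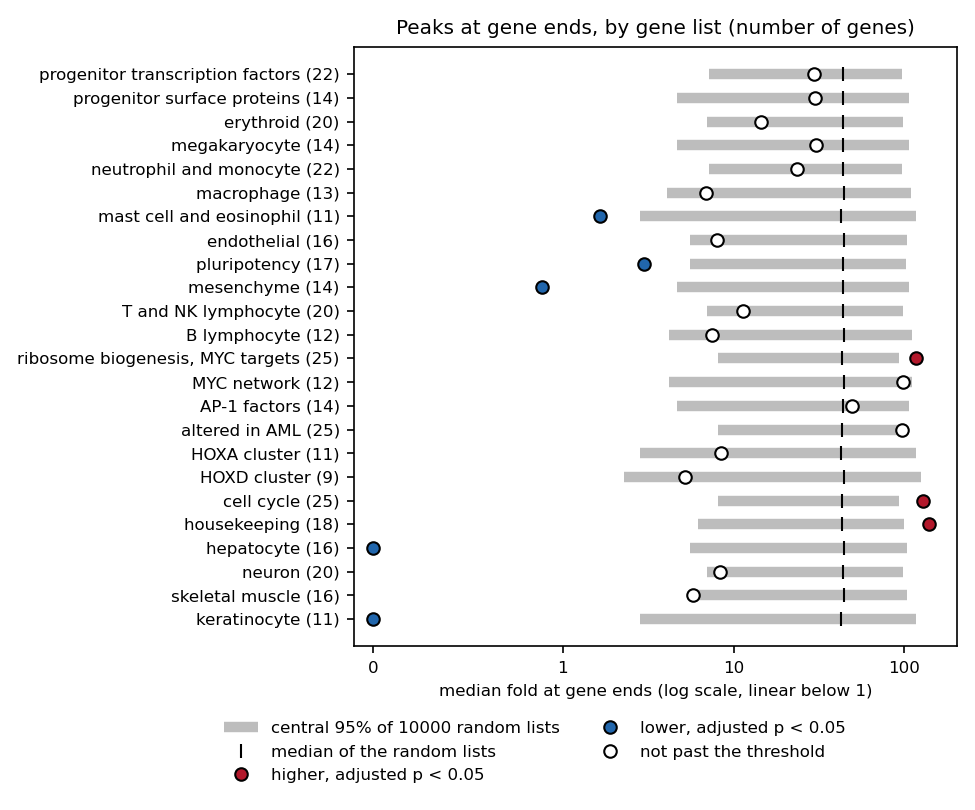
Median over the genes of each list of the highest fold enrichment within 1 kb of a gene end (horizontal axis, log scale, linear below 1), with the number of genes in brackets. Grey bars span the central 95% of 10000 random lists and ticks their median; housekeeping, cell cycle and ribosome biogenesis genes lie above (118 to 140-fold), and 5 lists lie below (0 to 2.99-fold).

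Distal peaks, with a summit more than 1 kb from every coding gene end, were denser around AP-1 factors and progenitor transcription factors than around random genes. The 22 progenitor transcription factors had a median of 23.2 distal peaks per 100 kb of sequence within 50 kb of the gene's ends, against 14.1 for random lists, and 14 of the 22 exceeded the upper quartile of all genes (19.9). Among them were MYB (34.1), FLI1 (32.0), ZBTB16 (31.5), IKZF1 (29.0), GATA2 (27.2) and RUNX1 (26.5), whereas KMT2A had 7.88. AP-1 factors, which respond to growth and stress signals, had a median of 23.7, and 14 of 14 exceeded the median of all genes (FOSL2 41.0, MAFF 28.8, FOS 28.0). Both lists passed the test (permutation p = 0.0002 and 0.0004, the former the smallest that these permutations can give; adjusted p = 0.0048 for each). HOXA5 (20.5), HOXA9 (21.3) and HOXA10 (20.1) of the progenitor list lie side by side and share distal peaks. They are among the 14 above the upper quartile, so the p-value of that list overstates the evidence to that extent. Neighbours in other lists, such as S100A8, S100A9 and S100A12 among neutrophil and monocyte genes, carry the same limit. Progenitor surface proteins (20.6; CD34 37.6), megakaryocyte genes (20.4; ITGB3 33.1) and neutrophil and monocyte genes (19.5; IRF8 33.2) missed the threshold (permutation test, adjusted p = 0.0528, 0.0564 and 0.0528). The first and last of these passed in 2 of 5 alternatives each, progenitor surface proteins within 20 kb and with matching on neighbouring genes (permutation test, adjusted p = 0.0224 and 0.0256), and neutrophil and monocyte genes with the more significant 50% of the peaks and within 20 kb (0.0032 and 0.0365).

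Around mesenchymal (6.78 per 100 kb), neuronal (7.55) and keratinocyte genes (6.11), distal peaks were sparser than around random genes (permutation test, adjusted p = 0.0264, 0.0256 and 0.0384). DCN had 3.51, DCX 3.00 and FLG 0.813, while PDGFRB had 33.1 and COL1A1 22.97. The remaining 16 lists did not pass: HOXA 20.5, HOXD 18.5, cell cycle 18.3, genes altered in leukaemia 16.9, housekeeping 16.7, erythroid 16.3, skeletal muscle 15.8, T and NK 15.8, MYC network 15.5, mast cell 15.3, ribosome biogenesis 15.3, endothelial 15.3, macrophage 13.5, pluripotency 13.4, B lymphocyte 12.3 and hepatocyte 10.7 (permutation test, adjusted p from 0.125 to 0.854). With the more significant 50% of the peaks, HOXA (permutation test, adjusted p = 0.0024) and cell cycle genes (0.0432) passed as higher, in that 1 of 5 alternatives only. The 11 HOXA genes lie side by side and share distal peaks, whereas random lists draw scattered genes. The HOXA p-value therefore overstates the evidence from what is a single locus. Of the lower calls, mesenchymal genes kept theirs in 1 of 5 alternatives, neuronal genes in 2 and keratinocyte genes in 3, and none did within 100 kb. The genes with the most distal peaks were RAB7A (89), LOC128462377 and SLC45A4 (87 each), RASA3 (85), PIK3CB (83), ANKRD33B and SCARB1 (80 each), MYH9 (79), and NOL4L and the blood transcription factor RUNX3 (75 each), against a median of 19 per gene.

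**Figure D3:**
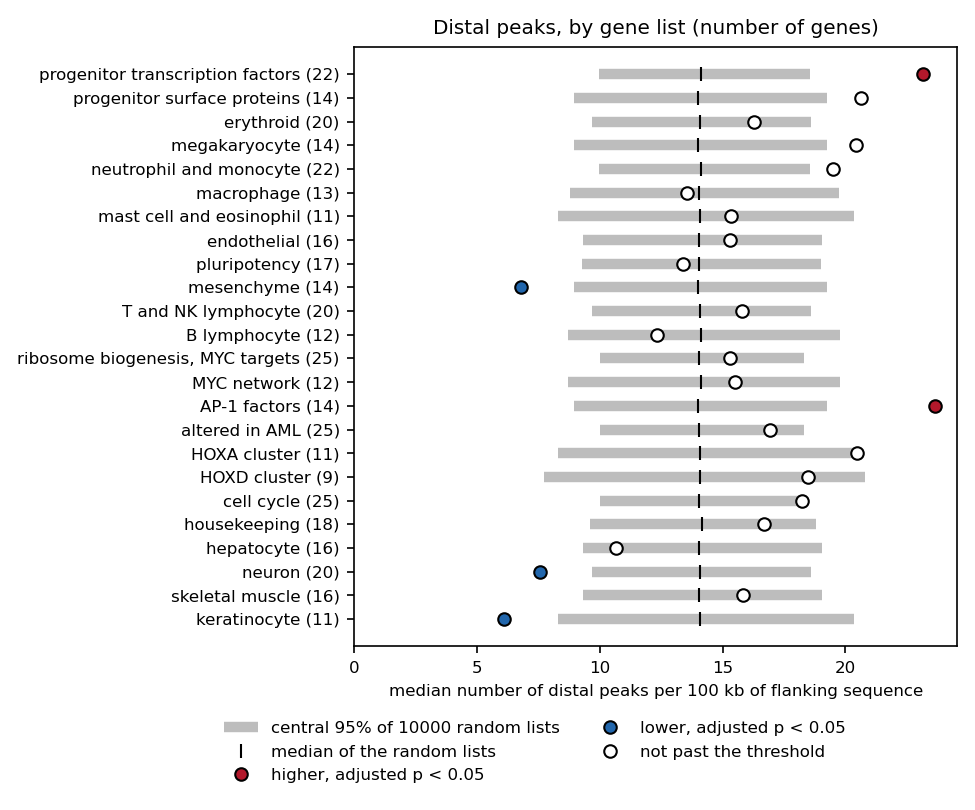
Median over the genes of each list of the number of distal peaks per 100 kb within 50 kb of the gene's ends (horizontal axis), with the number of genes in brackets. Grey bars span the central 95% of 10000 random lists and ticks their median; progenitor transcription factors (23.2) and AP-1 factors (23.7) lie above, and mesenchymal, neuronal and keratinocyte genes (6.11 to 7.55) below.

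Regulatory regions of blood genes named in advance were examined in 15 windows, each set against 10000 windows of the same shape at random coding genes. The random windows were placed from either end of a gene, drawn at random, whereas the 15 windows were placed from 5′ ends. Random windows that ran past a chromosome end were kept. Both can raise the percentiles given here. Of the 15, SPI1, TAL1, GATA2 and RUNX1 ranked highest by the percentile of their coverage among random windows. At SPI1 (chromosome 11, 47338547 to 47408547), which encodes the myeloid factor PU.1, 17 peaks covered 72.2% of the window (99.9th percentile). A 109-fold peak lay at the 5′ end, a 96.0-fold peak of 10074 bp (47387410 to 47397483) reached across its upstream region, and a 17851 bp peak covered its 3′ part. The highest peak of the window, 225-fold, lay inside the neighbouring gene SLC39A13. TAL1 (chromosome 1) was covered by a single peak of 28905 bp from 47211259 to 47240163 (105-fold), and 59.1% of its window lay in peaks (99.3rd percentile). A peak of 114-fold lay 53.0 kb downstream of the TAL1 5′ end.

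At GATA2, a factor required for blood stem cells, a 23245 bp peak (chromosome 3, 128476157 to 128499401, 54.9-fold) covered the gene. The highest peak of that window (67.3-fold, 7616 bp, 128602109 to 128609724) lay 115 kb upstream, in intergenic sequence, and 49.1% of the window lay in peaks (98.7th percentile). RUNX1 (chromosome 21) held 117 peaks covering 40.9% of its 330-kb window (98.4th percentile). The highest of them (113-fold, 35025252 to 35029327) lay inside the gene, 22.4 kb from its 5′ end, and an 11476 bp peak of 101-fold (34880437 to 34891912) lay 161 kb from that end. Coverage was at the 96.3rd percentile for CEBPA, the 95.8th for the alpha-globin cluster, the 93.9th for LMO2, the 92.7th for CD34, the 92.5th for the HOXA9 window and the 90.4th for the beta-globin cluster. GATA1 lay at the 88.0th and MEIS1 at the 81.8th. KIT, the stem cell factor receptor, did not stand out (52 peaks, 14.4% covered, 56.6th percentile), with peaks of 62.7-fold 86.5 kb upstream and 59.8-fold at its 5′ end.

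Globin genes lay among strong distal peaks. Near HBE1, the embryonic beta-like globin gene, the highest peak (82.9-fold, chromosome 11, 5280035 to 5281351) lay 10.8 kb upstream, in the interval of the beta-globin locus control region. At the genes themselves, the fetal gene HBG2 had a 37.8-fold peak of 5965 bp that also covered an end of HBG1. The adult genes HBD and HBB had peaks of 27.7-fold and 11.4-fold at an end, and HBE1 8.78-fold. The HBB peak (5224472 to 5225859) was the only one at that gene and covered 24.6% of it, so it reached only 1 of its ends. Of the beta-globin genes, only HBE1 was given a strand here. Which end of HBB is the start was not told apart, so this peak need not mark the HBB promoter. In the alpha-globin window the 2 highest peaks lay at the ends of the neighbours POLR3K and SNRNP25 (196-fold) and NPRL3 (107-fold). Inside NPRL3, whose introns hold alpha-globin enhancers, peaks of 86.4-fold (chromosome 16, 96137 to 97704) and 64.5-fold (112585 to 114765) were called.

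MYC itself (chromosome 8, 127735434 to 127742951) lay almost wholly under peaks. A 77.1-fold peak of 7399 bp (127733839 to 127741237) began 1595 bp before the annotated gene start, with its summit 1270 bp before it. A 14.5-fold peak (127741281 to 127743743) followed after a gap of 43 bp, and together they covered 99.4% of the gene. Within 100 kb on each side of the start, peaks covered 14.7% of the window (29 peaks, 55.65th percentile). The far downstream interval from 129335434 to 129735434, which holds the blood enhancer cluster of MYC, had 76 peaks covering 19.0% (82.7th percentile). Its highest peaks were 68.9-fold at 129420180 to 129423975, 65.8-fold at 129581484 to 129583951 and 50.9-fold at 129535031 to 129537069, 1685, 1847 and 1800 kb from the gene start. Whether any of these differs with ectopic MYC could not be tested on a pooled list. Any added copies of MYC sequence, in whichever libraries carry them, cannot be separated from the gene's own signal.

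**Figure D4:**
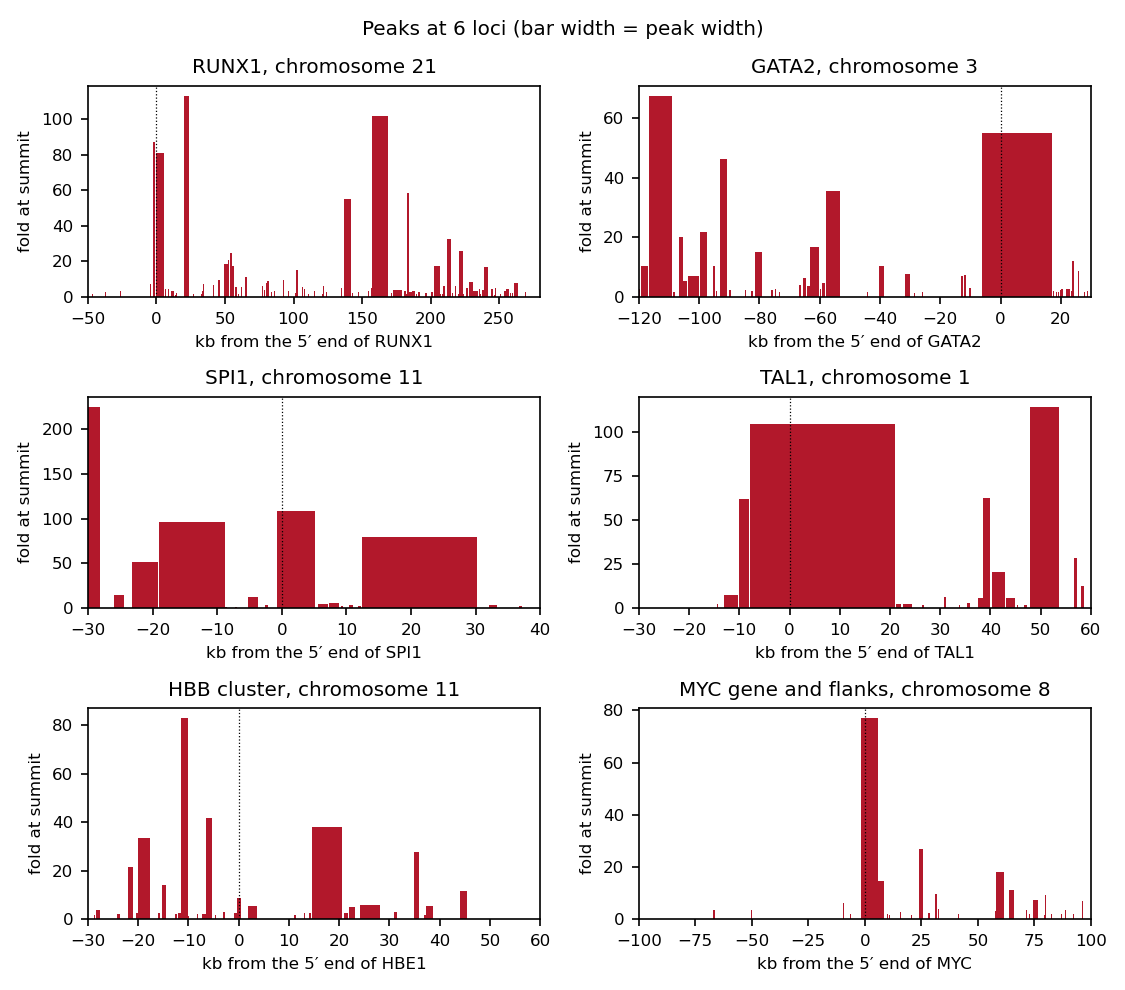
Peaks at 6 loci as bars, each as wide as its peak, with the fold enrichment at the summit (vertical axis) against distance in kb from the 5′ end of the named gene (horizontal axis, positive in the direction of transcription; dotted line at the 5′ end). GATA2 and TAL1 lie under single peaks of 23245 and 28905 bp, and the highest peaks of the GATA2 and beta-globin windows lie 115 and 10.8 kb upstream.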

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

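Of these alternatives, 3 were chosen after seeing the data: summits nearest to the gene itself, matching on gene length and leaving out the X chromosome. The excess of summits at gene ends stayed between 2.11-fold (windows of 2.5 kb) and 3.87-fold (more significant 50%), on 23 of 23 chromosomes under all 4 alternatives. That 50% left 154539 of 308732 peaks, by construction, and merging overlaps changed nothing. The housekeeping, cell cycle and ribosome biogenesis lists passed as higher at gene ends in all 7 alternatives (adjusted p from 0.0048 to 0.0472). Genes altered in leukaemia also passed in 2 of the 7, with the gene's own summits and without the X chromosome (permutation test, adjusted p = 0.0472 and 0.0272). The 5 lists lower there became 0 with the more significant 50% and 0 with 0.5 kb windows, and 2 with 2.5 kb windows, 2 with any overlap, 2 with the gene's own summits and 2 with length matching. Hepatocyte genes passed in 5 of the 7, mesenchymal and keratinocyte genes in 3 each, and pluripotency and mast cell genes in 1 each. For distal peaks, progenitor transcription factors and AP-1 factors passed in all 5 alternatives (adjusted p up to 0.018). The 2 higher lists became 5 with the more significant 50% and 4 within 20 kb, and the 3 lower lists became 1, 1 within 20 kb and 0 within 100 kb. Matching on neighbouring genes lost mesenchymal genes (permutation test, adjusted p = 0.163) and gained progenitor surface proteins (adjusted p = 0.0256), and length matching lost keratinocyte genes (adjusted p = 0.0595). The causes were not tested. No call reversed direction.

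No paired analysis was possible because the list gives no value for any library. For the same reason the alternatives with a replicate block, without each library and with both untreated lines were not run. The motif alternatives, the gene's own 5′ end and CpG matching were not run because sequence and strand were not used here. Pooled depth limits weak peaks: at 124 overlapping reads, the weakest fold of 1.32 has a counting interval from 1.10 to 1.57.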

Other observations

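All comparisons in this part were chosen after the data were seen. Gene families split sharply at gene ends. Ribosomal protein genes (78 of 80 with a summit, median 119-fold), mitochondrial ribosomal proteins (75 of 77, 112-fold), replication-dependent histones (48 of 63, 118-fold) and ZNF zinc finger genes (426 of 477, 86.6-fold) lay above random genes by median fold. By the share of genes with a summit, histones (76.2%) lay below all coding genes (83.0%). Olfactory receptors (63 of 392), bitter taste receptors (3 of 25), keratin-associated proteins (17 of 94), type I interferons (5 of 16) and killer and leukocyte receptors (19 of 41) had medians of 0. Each of the 9 families differed from random lists (permutation test, adjusted p from 0.000225 to 0.0016). The former comes from the smallest permutation p that 10000 random lists can give, 0.0002. Random lists draw scattered genes, so for families whose members lie side by side these p-values overstate the evidence. Among short RNA genes, 85.1% of 443 tRNA genes had a peak, against 9.33% ± 2.39 (SD) after 100 circular shifts, with 58.4% of 154 snRNA genes (11.5% ± 3.25), 30.04% of miRNA genes (9.40% ± 0.951) and 19.7% of snoRNA genes (9.40% ± 1.01). Pseudogenes stayed at 17.2% (16.9% ± 0.367). Here too, the shifts did not leave out sequence in which no peak can be called. Among genes more than 5 kb from a coding gene end, 80.8% of 334 tRNA, 55.2% of 134 snRNA, 19.2% of 1346 miRNA and 10.01% of 889 snoRNA genes had a peak. No shifted share was computed for these genes alone, so whether the snoRNA excess persists there cannot be told.

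Set against 63 genes of 4 non-blood lists (hepatocyte, neuron, skeletal muscle, keratinocyte) rather than against all genes, 4 of the 12 lists were more open at their ends. The hepatocyte and keratinocyte lists were already known to be low when these genes were chosen, so part of each difference restates the low values of the control. On the log2 scale with a floor of 1, megakaryocyte genes were higher by 2.41 (SE 0.51), progenitor surface proteins by 2.28 (SE 0.63), neutrophil and monocyte genes by 2.25 (SE 0.43) and progenitor transcription factors by 2.095 (SE 0.59; permutation test, adjusted over 12 lists, p = 0.00108, 0.00135, 0.00048 and 0.00132). Erythroid genes were at 1.27 (SE 0.52; permutation test, adjusted p = 0.0525). Endothelial, macrophage, T and NK, B lymphocyte, mast cell, mesenchymal and pluripotency genes did not differ detectably (adjusted p from 0.113 to 0.861). By any overlap in place of the summit and the same permutation test, 6 of the 12 passed, erythroid (1.83, adjusted p = 0.00463) and endothelial genes (1.61, adjusted p = 0.0209) included. Distal density passed for 8 of 12: progenitor surface proteins (23.1 against 11.6 peaks per 100 kb), progenitor transcription factors (22.2), megakaryocyte (21.9), neutrophil and monocyte (19.6), mast cell (17.9), T and NK (17.4), erythroid (16.8) and endothelial genes (16.5). Neuronal and keratinocyte genes of the control were already known to be sparse in distal peaks, and mast cell, T and NK, erythroid and endothelial genes had not differed from random genes (permutation test, adjusted p from 0.529 to 0.757), so these passes in part restate the control. Macrophage, B lymphocyte, pluripotency and mesenchymal genes did not pass (adjusted p from 0.334 to 0.654).

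The highest peaks of the list were mostly not at regulators of blood. The first, 4635-fold on chromosome 1 (628924 to 635084), covers a run of nuclear copies of mitochondrial genes beside LOC102724250, and others lie near AMPD3 (1713-fold), MYO16 (216 kb away, 1386-fold) and KCNJ18 (817 kb away, 742-fold). Of the 20 highest, 8 (40%) overlapped a mitochondrial pseudogene or a ribosomal RNA gene, against 0.0153% of all peaks, so reads shared among copies of such DNA may account for part of them. That share is under the 50% asked of a main cause, a bar set after these peaks had been seen, and the definition of mitochondrial copies was narrowed later without changing the share. The other 12 stay open, and no biological explanation was tested.

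Peaks were wide at progenitor transcription factors: the widest at each of the 22 progenitor transcription factors had a median of 5.75 kb, against 2.43 kb for random lists matched on highest fold and gene length, and 13 of the 22 genes had a peak wider than 5 kb, against 8.72% of all genes. Higher signal or gene length alone is argued against, since the list lay at percentile 100 of the matched lists (permutation test, adjusted p = 0.00096, and 0.0016 with finer bins or fold alone, from the smallest p possible). Open growth genes were not all wide, since the higher of the ribosome biogenesis and cell cycle lists lay at percentile 52.7. Housekeeping genes (99.2) were, however, so width as a trait of some open growth genes stays open. The MYC network (99.9) was wide too, though it had not passed as higher at gene ends. Progenitor surface, megakaryocyte, neutrophil and monocyte, endothelial, AP-1 and leukaemia lists were wider under all 3 matchings, but so were housekeeping, MYC network, pluripotency and mesenchymal genes, so width is not particular to blood, and erythroid, HOXD and hepatocyte calls changed with the matching. Merging of nearby elements by the caller at high pooled depth, and peaks added together from different days or treatments, stay open as untested.

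The widest peaks included one of 51.7 kb over SYN3 and TIMP3 (15.9-fold) and others over LMNA and SEMA4A (36.7 kb), SLC16A3 and CSNK1D (34.1 kb), MCL1 (32.5 kb), TAL1 (28.9 kb), SH2B3 (28.5 kb), ALAS1 (27.0 kb) and GATA2 (23.2 kb), named after their widths were seen and leaving out peaks over ribosomal RNA genes and mitochondrial copies.

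MYC had a greater share of its length covered than 98.3% of 743 genes within 1.5 times of its length and highest fold, whose median was 30.7% covered. The peak began 1595 bp before the gene start, but this does not bear on coverage inside the gene, since a peak at the native promoter could reach there in any case. Reads from an ectopic MYC copy without flanking sequence could therefore account for the coverage, and this explanation stays open, as a pooled list cannot separate them. Doxycycline treatment, day and line also stay open as biological explanations that were not tested.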
